A study of Mus musculus with 2 samples.

How the data were processed

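The study used ChIP-chip, in which protein is crosslinked to DNA, the protein of interest is pulled down with an antibody, and the DNA that comes with it is labelled and hybridised to an array of probes. Per the labels' protocols, whole mouse embryos of embryonic day 14.5 were fixed in 3% paraformaldehyde for 10 minutes at 37 degrees Celsius, lysed and sonicated. Chromatin from pools of 10 embryos was immunoprecipitated with an antibody against the FLAG peptide. On each of 2 two-colour Agilent arrays, DNA from embryos whose cyclin D1 carries FLAG and HA tags was labelled with Cy5, and DNA from wild-type embryos, which have no FLAG tag, was labelled with Cy3. The wild-type immunoprecipitate on the same array therefore serves as the background, though in the other dye and from other embryos. Both arrays have the same dye orientation.

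The deposited tables hold 1 log2 ratio for each feature number of an array. Agilent Feature Extraction 9.1 is named in the submitters' processing notes. The background correction, the normalization, the filters, the probe annotation and the genome build are not given in the sources used here. The log base and the scaling were therefore worked out from the values. The commonest value of each array was taken as a ratio of 1 to 1, and the next commonest values lay at distances from it that are log2 of simple fractions, such as 3 to 2 at 0.585 and 5 to 4 at 0.322. This sets the base of the deposited log2 values to 2. The deposited values equal the log2 ratio of 2 whole-number signals plus 1 constant per array. With the commonest value read as 1 to 1, that constant was the negative log2 of 251 over 221 on array 1. On array 2 it was the negative log2 of 176 over 135. These are divisions by 1.136 and by 1.304. On array 2 steps of 2 to 1 and 4 to 3 were among the most frequent values. On array 1 neither was, and the steps were 3 to 2, 5 to 4, 3 to 4 and 7 to 6. The reading of the commonest value of array 1 as 1 to 1 is therefore doubtful. A reading as 2 to 1, with another factor, was not run and stays open. The medians of the recovered numerator and denominator signals had ratios of 1.138 and 1.307, close to those factors. This largely follows from the deposited medians of -0.0097 and -0.014, so it is no separate check of the constants. A correction of the ratio by signal or by slide position would not leave fractions of whole numbers, so none is present in the values that gave such fractions.

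The direction of the ratio is not stated. The numerator is likely the Cy5 channel with the tagged embryos, because the sample titles name the tagged embryos first, because they are channel 1, and because Agilent's own ratio is red over green. Positive values are called higher here, meaning a larger numerator. If the ratio was formed the other way, every higher and lower below exchange places.

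Each array's values were centred on the median, which was -0.0097 on array 1 and -0.014 on array 2, with no loess or quantile step, because in ChIP many probes can truly shift one way. For each probe, the fraction with the smallest whole-number terms that gave the deposited value within single-precision rounding was found (continued fractions, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0). Its terms are called the recovered signals. They are in lowest terms, so a pair of signals with a common factor comes back smaller than it was. On array 1, 67.6% of the probes gave fractions whose terms had a geometric mean of at most 300, and on array 2 63.4% did. After random noise with an SD of 0.001 log2 units was added to the values, 0.669% and 0.647% did. For terms with a geometric mean of up to 1000 the shares were 90.3% and 85.2%, against 7.31% and 7.33% with the noise, so signals above that are not resolved. Values that are no fraction of whole numbers would mostly land there too, so whether those probes are bright was not measured. In the recovered fractions of array 1, 22.6% of the numerators and 52.2% of the denominators were even, where 33.3% is expected of whole numbers in lowest terms. Signals of array 1, and its division by 1.136, therefore carry a further uncertainty of a factor of 2. The centred ratios do not depend on that factor. The grouping of the probes of array 1 by signal, and limits set on their signals, do depend on it, probe by probe. The 2 signals of a probe were summarised by their geometric mean, and the probes of an array were divided into 10 equal groups by it.

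The recovery and the counts were tested on simulated data. In simulations with the probe number and the recovered signals of each array, every fraction with terms of a geometric mean up to 300 came back exactly (100%). The signals themselves came back exactly for 61.8% of those probes on array 1 and 62.4% on array 2. The simulations used the constants that follow from reading the commonest value as 1 to 1, so they do not test that reading. They came back within 2-fold for 76.7% and 77.1%, so the remaining recovered signals were more than 2-fold too small. With 5% of the probes raised by 1.5 log2 units, 83.5% of them on array 1 and 82.9% on array 2 were counted as 2-fold or more higher. With none raised, 6713 probes were 2-fold higher and 6456 lower on array 1, and 7213 and 6871 on array 2. The ratios were 1.04 and 1.05. The simulated noise had the same size in both channels, so a ratio near 1 follows from its design. It also gave more lower probes than the 4963 and 4842 of the data. The simulation therefore cannot tell whether real noise could give more higher than lower probes.

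The 2 arrays are different designs. They share 237177 feature numbers, but the ratios of the same number on both had a Pearson correlation of 0.0087. A probe of one design could stand under another number on the other, but without an annotation none could be matched. Each value is therefore treated as 1 measurement without replicates, and no test of single probes across arrays was made. The arrays were compared only by their shares of probes and by their slide maps. Shares of probes are given with exact (Clopper-Pearson) 95% binomial intervals, and ratios of 2 counts with the interval that follows from them. These intervals cover counting error over probes only, and neighbouring promoters, fragments or spots can make probes depend on each other. The small number of arrays limits the precision of every statement about the embryos. Whether the 2 arrays received the same immunoprecipitates or separate ones is not given in the sources used here.

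The files do not pair feature numbers with genes or positions, and the gene table at hand holds no feature numbers. The planned results by 3-probe window, by gene, by the 16 fixed gene lists, at the cyclin D1 locus, by chromosome, by distance between probes and around transcription starts were therefore not analysed here. The rule for named items, fixed before the data were examined, was then the 5 highest and 5 lowest probes of each array. Since a bare number identifies no locus, only the highest and the lowest of each array are named. Alternatives set before the data were examined were no centring, other thresholds, a common scale for both arrays, and each array alone. Alternatives by signal, by slide position and by signal trend were chosen after seeing the data. For slide positions, feature numbers were read as rows of 456 spots. Among the distances of 101 to 1500 feature numbers, 912 and 456 gave the highest correlation between values on both arrays, at 0.024 for both distances on array 1 and at 0.029 and 0.027 on array 2. A local median was taken over blocks of 20 by 20 spots, and a running median by signal over 100 equal groups of probes. Intervals were computed with scipy 1.17.1.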

Results

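Cyclin D1 is a D-type cyclin, known as the activating partner of the kinases that phosphorylate the retinoblastoma protein. The study asked whether it also sits on DNA in the living mouse. To this end, DNA pulled down with an anti-FLAG antibody from embryos with FLAG- and HA-tagged cyclin D1 was compared with DNA pulled down in the same way from wild-type embryos at embryonic day 14.5. The 2 samples, which form 1 group, are 2 two-colour arrays of different design, each carrying both immunoprecipitates. Array 1 lists 237195 probes, of which 234157 have a value. Array 2 lists 237185 probes, of which 233490 have a value. No probe could be matched between the arrays, so no value below has a replicate SD. The probes are known only by feature number, and no gene, chromosome or position is assigned to any of them here.

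On both arrays, more probes were enriched in the numerator channel, likely the tagged embryos, than in the other. Probes with a log2 ratio of at least 1 above the array median, a 2-fold enrichment, made up 6.24% of array 1 (14608 probes, 95% interval 6.14 to 6.34%). On array 2 they made up 6.31% (14728 probes, 6.21 to 6.41%). Probes 2-fold or more below the median, the opposite tail of the same hybridisation, made up 2.12% of array 1 (4963 probes, 2.06 to 2.18%) and 2.07% of array 2 (4842 probes, 2.02 to 2.13%). There were thus 2.94 higher probes for each lower one on array 1 (2.85 to 3.04) and 3.04 on array 2 (2.94 to 3.14). Over both arrays, 29336 probes were higher and 9805 lower, and the difference of 19531 probes is 4.18% of all probes measured. The tagged embryos were labelled with Cy5 on both arrays, so tag and dye cannot be told apart.

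The 2 arrays gave nearly the same shares. Array 2 exceeded array 1 by 0.069 percentage points among higher probes, with a 95% interval from -0.070 to 0.21 points by the normal approximation for these large counts. Among lower probes the difference was -0.046 points, from -0.13 to 0.036. The arrays are different designs whose probes could not be matched, so this compares 2 sets of probes and is not a repeat of known measurements.

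**Figure D1:**
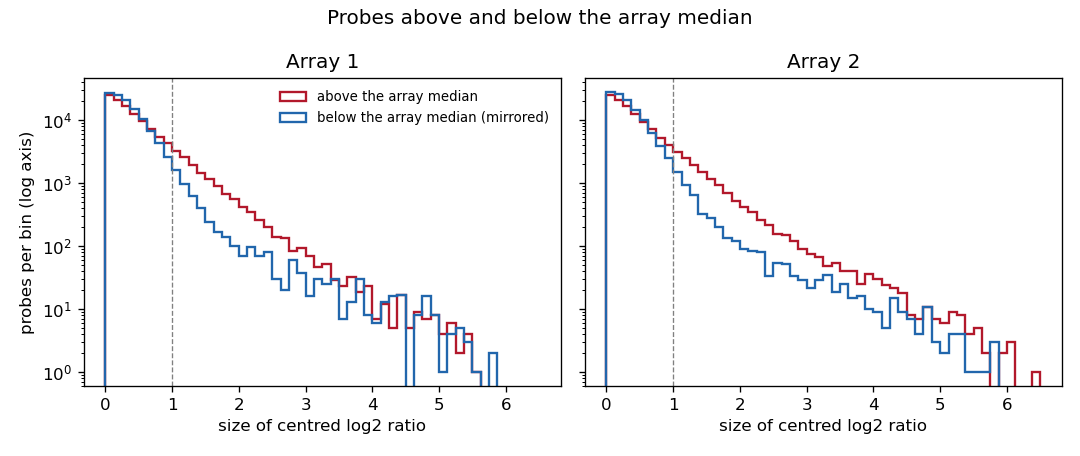
Number of probes per bin (log axis) against the size of the centred log2 ratio, for probes above the array median and, mirrored, for probes below it, on array 1 and array 2. Beyond the dashed line at 2-fold, the higher probes (14608 and 14728) outnumber the lower ones (4963 and 4842), and the curves come together again at the largest ratios on array 1.

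The ratio of higher to lower probes varied with the fold required. At 1.5-fold or more, 14.7% of the probes of array 1 were higher and 9.22% lower, and 14.5% and 8.70% of array 2. At 3-fold or more, the higher probes numbered 4511 against 1223 lower on array 1 and 4796 against 1247 on array 2, which is 3.69 and 3.85 to 1. At 4-fold or more the counts were 2067 against 725 and 2311 against 706. At 8-fold or more, 381 probes were higher and 259 lower on array 1, a ratio of 1.47 (1.25 to 1.73), and 555 were higher and 250 lower on array 2, a ratio of 2.22 (1.91 to 2.59). At 16-fold or more, array 1 had 87 higher and 100 lower probes, with a ratio of 0.87 whose interval of 0.65 to 1.17 includes 1. Array 2 had 167 and 79, a ratio of 2.11 (1.61 to 2.80).

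How well a probe was measured depends on its signal, which could be recovered from the deposited ratios only in lowest terms. The groups with the lowest recovered signals therefore hold dim probes and also brighter ones whose signals share a common factor. On array 1 the groups are also uncertain by the factor of 2 given above for its signals. The 10% of the probes of array 1 with the lowest recovered signals had a median of 9.54. Of these, 12.6% were 2-fold higher and 8.01% 2-fold lower, a ratio of 1.58 (1.49 to 1.67). In the ninth group of 10, with a median signal of 674, 10.0% were higher and 0.436% lower, a ratio of 23.1 (18.9 to 28.4). On array 2 the 10% with the lowest recovered signals had 14.6% higher and 8.17% lower probes, a ratio of 1.79 (1.69 to 1.89). The ninth group, with a median signal of 980 and therefore partly beyond the resolved range, had 8.12% higher and 0.325% lower probes, a ratio of 24.96 (19.8 to 31.8). The share of higher probes was lowest in the fourth group on both arrays, at 3.10% and 3.51%, and rose again with signal up to the ninth. In the tenth group, whose signals lie about at or beyond the limit of what could be resolved, 7.73% were higher and 0.384% lower on array 1, a ratio of 20.1 (16.3 to 25.1). On array 2, 3.87% were higher and 0.638% lower there, a ratio of 6.07 (5.10 to 7.26).

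**Figure D2:**
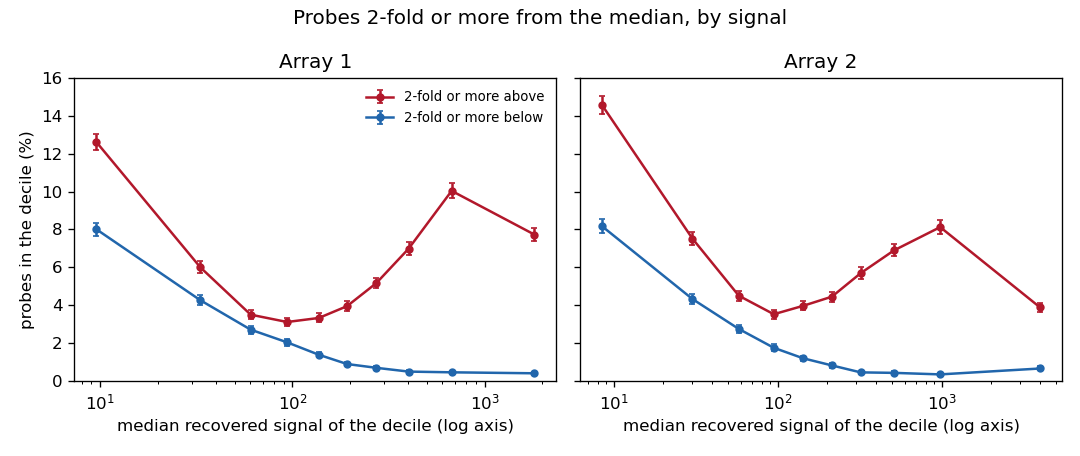
Share of probes 2-fold or more above and below the array median in each of 10 equal groups of probes, against the group's median recovered signal (log axis), on array 1 and array 2. Bars are exact 95% binomial intervals, and the share of lower probes falls from 8.01% in the first group to 0.436% in the ninth on array 1 and from 8.17% to 0.325% on array 2, where it is 0.638% in the tenth. The share of higher probes has a second peak in the ninth group, at 10.0% and 8.12%, and the ninth group of array 2 and the tenth of both arrays lie partly or wholly beyond the resolved signals.

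In the brighter 50% of the probes, 6.77% of array 1 were higher and 0.569% lower, 11.9 to 1 (11.0 to 12.9). On array 2, 5.80% were higher and 0.521% lower, 11.1 to 1 (10.3 to 12.1). An enriched probe is also brighter, which favours the higher side in such a split. This split also counts every unresolved probe as bright, though the brightness of those was not measured. When the brighter 50% were chosen by the denominator signal alone, which favours the lower side, the ratios were 6.19 (5.80 to 6.61) and 6.03 (5.62 to 6.47). The brighter 50% held 75.3% of the surplus of higher over lower probes on array 1 and 62.4% on array 2 in the first split, and 56.7% and 46.1% in the second.

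The probes with the most extreme ratios had a recovered signal of only 1 or 2 in 1 channel. Neither the size nor the order of their ratios is precise. The highest probe of array 1, number 7893, had a centred log2 ratio of 5.53, from recovered signals of 52 and 1. The highest of array 2, number 74742, had 6.41, from signals of 110 and 1. The lowest probe of array 1, number 3920, had -5.85, from signals of 1 and 51, a value that a further probe of that array shared. The lowest of array 2, number 39900, had -5.86, from signals of 1 and 45. In the other 4 highest and 4 lowest probes of each array, 1 channel likewise had a recovered signal of 1 or 2.

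Among probes with a recovered signal of 100 or more in both channels, the range was smaller. These were 140626 probes on array 1 and 139877 on array 2. On array 1 it is uncertain which probes pass this limit, since its signals carry an uncertainty of a factor of 2. This holds for its highest probe too. The highest of them was 13.7-fold above the median on array 1, with recovered signals of 1639 and 106. On array 2 it was 26.6-fold above, with signals of 10872 and 317 that lie beyond the resolved range. The lowest were 10.2-fold and 14.3-fold below it. On array 1, 7783 of these probes were 2-fold higher and 773 lower, and 721 were 4-fold higher and 33 lower. On array 2, 6650 were 2-fold higher and 784 lower, and 570 were 4-fold higher and 39 lower.

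The ratio also varied with the place of a probe on the slide, by less than the 2-fold threshold. Medians of blocks of 20 by 20 spots ranged from -0.11 at the 5th percentile to 0.10 at the 95th on array 1, and from -0.13 to 0.12 on array 2. Their SD was 0.065 and 0.075 log2 units, against 0.027 on both arrays after the values were shuffled over the spots. The 621 blocks of array 1 correlated with those of array 2 at a Pearson r of 0.48 (Spearman 0.48). That correlation is across blocks, which are not independent. After subtracting the block median, there were 3.10 higher probes for each lower one on array 1 (3.00 to 3.20) and 3.38 on array 2 (3.27 to 3.50).

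**Figure D3:**
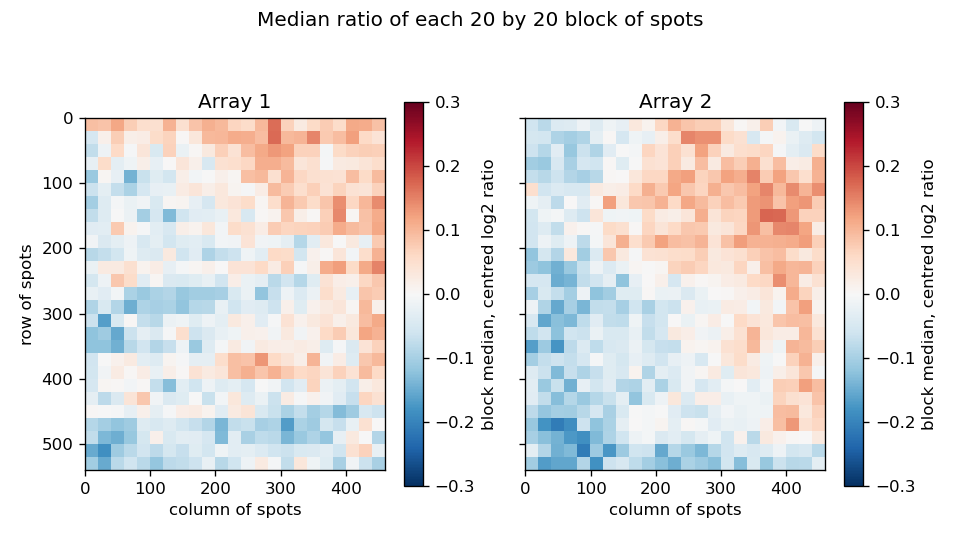
Median centred log2 ratio of each block of 20 by 20 spots (colour, from -0.3 to 0.3) by row and column of spots on the slide, for array 1 and array 2. On both arrays the last row strip (-0.058 and -0.10) and the first column strip (-0.060 and -0.069) have medians below 0, and the last column strip (0.061 and 0.044) has a median above it. The last row strip and the last column strip are narrower than 20 spots.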

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

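Alternatives by signal, slide position and signal trend were chosen after seeing the data. Higher probes outnumbered lower ones under all 12 alternatives, over both arrays together, with ratios from 1.63 to 11.5 around the reported 2.99. At 1.5-fold, 68294 probes were higher and the ratio was 1.63. At 3-fold 9307 were higher, and at 3 robust SDs 14462, with ratios of 3.77 and 3.83. Each array alone gave 14608 to 14728 higher probes and a ratio of 2.94 to 3.04. The brighter 50% of the probes held 14701 higher probes at a ratio of 11.5. Signals of 100 or more in both channels left 14433 at 9.27, and the brighter 50% by denominator signal left 11988 at 6.11. Those 3 settings test fewer probes, and on array 1 they rest on signals that are uncertain by a factor of 2. No centring, a common scale for both arrays, and removal of the slide or signal trend gave 28660 to 29431 higher probes. The 4 named probes moved by less than 1 SD of their array under the 3 settings run on them. Those settings only change which median is subtracted, by amounts small beside that SD, so this is no check of the probes' ratios. Depth of signal is 1 limit among others: 6.46% of the probes of array 1 and 7.28% of array 2 had a recovered signal of 10 or less in at least 1 channel. These shares also count brighter probes whose signals share a common factor. Settings fixed in advance for windows, genes, gene lists, the cyclin D1 locus, chromosomes, neighbouring probes and transcription starts were not run, because feature numbers could not be tied to genes or positions.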

Other observations

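The tests of dim spots behind the 2-fold excess and of probe sequence were chosen only after the results were seen, and those of the slide trend, the signal trend, the zero, the 8-fold probes and the slide maps after the values had been examined but before their own result.

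Probes 2-fold or more above the array median outnumbered those below it on both arrays. Noise of dim spots is argued against as the whole cause, since the lower of the ratios of the 2 arrays was 6.03 among the 50% of probes with the brighter denominator signal, a split that favours the lower side, and 11.1 in a split by both signals, which favours the higher side. On array 1 these splits rest on signals that are uncertain by a factor of 2. A trend of the median across the slide is argued against too, since the lower ratio was 3.10 after the local median was removed. Subtracting a median removes only a shift of the centre, so a change of spread or skew with position or signal was not tested. Removing a smooth dye trend of the median with signal left a ratio of 3.06, and a misplaced zero would have to be off by 0.197 log2 units on array 1 and 0.212 on array 2, where 66.0% and 67.5% of the probes would then lie below zero. A dye bias by probe sequence stays open, since 0 of the 2 arrays have the dyes the other way round. It cannot be told apart from enrichment by the tagged protein, which remains untested. The channels also hold different embryos and different immunoprecipitates. A difference between these apart from the tag was not tested and stays open too.

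Probes 8-fold or more from the median may largely be dim spots on both sides. Enrichment would raise the larger of a probe's 2 signals above the probe's own baseline, which is not known here. Among these probes the larger recovered signal was below the median larger signal of the array for at least 88.2% on either side of either array. Its median was 27 among the higher and 17 among the lower probes of array 1, against 185 over all probes, and 28 and 17 on array 2, against 206. Recovered signals are in lowest terms in both sets. That comparison is with other probes, so it cannot tell noise from enrichment of a probe with a low baseline. Strong enrichment over a nearly empty channel stays open for dim probes and for the remaining ones. More of the 8-fold probes were higher than lower, 381 against 259 on array 1 and 555 against 250 on array 2. On array 1, the smaller of the 2 signals had a median of 118 among probes 2-fold or more higher, of 10 among those 4-fold or more higher and of 2 among those 8-fold or more higher, and on array 2 these medians were 74, 5 and 1.

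The slide maps of the 2 arrays rose and fell together. Of the 621 circular placements of one map on the other, 0.161% (the aligned one alone) gave a correlation as high as 0.484, but the next highest reached 0.483. This is consistent with an effect of position on the slide. A similar arrangement of probes on both designs was not tested and stays open. The same feature number on both arrays had ratios with a Spearman correlation of 0.014 before the local median was removed and 0.0036 after it.

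Spots with no value were 1.28% of array 1 and 1.56% of array 2. Within 20 spots of the slide's edges they made up 1.78% and 1.92%, against 1.19% and 1.49% inside. The median recovered signal was 131 at the edges and 169 inside on array 1, and 138 and 183 on array 2.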
